A study of Mus musculus with 28 samples.

How the data were processed

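RNA of sorted mouse macrophages was measured with MARS-seq, which counts the 3′ ends of polyadenylated transcripts by unique molecular identifiers (UMIs), in 28 libraries of 8 groups. Cx3cr1-gfp/+ mice were lethally irradiated and received bone marrow that carried a floxed human DNMT3A mutation allele, either with Vav-Cre (mutant), which recombines in blood-forming cells, or without it (control). At 16 weeks after transplantation, GFP-positive cells of the host and GFP-negative cells derived from the donor marrow were sorted from the brain parenchyma (called microglia in the labels) and from the leptomeninges. Parenchyma was digested and freed of myelin on Percoll, and leptomeningeal cells were washed off the surface of the digested intact brain, with actinomycin D to limit transcription during handling. Groups of 4 libraries were donor microglia, host microglia and donor leptomeningeal cells of each genotype, and host leptomeningeal cells had 2 libraries per genotype. The labels do not say that the libraries are separate animals, so p-values measure the spread between these libraries.

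The authors deposited a single table with a row per gene symbol and, per the file headers, a raw, a normalized and an rlog column for each library. The raw columns hold UMI counts per gene as deposited, on the mm10 genome build per the submitters' processing notes, and the aligner is not given in the sources used here. The deposited normalized columns hold signal as counts divided by a size factor per library, and their size factors equalled recomputed median-of-ratios factors within 0.001 in 28 of 28 libraries. The deposited rlog columns hold log2 values, whose rank correlation with the counts across genes was at least 0.9716 within each library. Only the counts were used for the tests, and every CPM value (UMIs of a gene scaled to a common library total) was computed from them. The table held 14617 genes, each with at least 6 UMIs in its best library, and 14370 of the symbols were found in GENCODE M21, which gave chromosome positions on mm10.

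Totals ran from 479077 to 3066506 UMIs per library with a median of 1634653.5. A gene with 0 UMIs could still have been present at up to 0.97831 CPM in the deepest library and 6.262 CPM in the shallowest, the level of 3 UMIs, and these limits cover counting error only. Genes were kept by edgeR's filterByExpr with the 8 groups, which left 12327. The main test was edgeR's quasi-likelihood test with robust dispersions, TMM scaling and 1 mean per group over all 28 libraries, with Benjamini-Hochberg (BH) adjustment at 0.05 over the genes tested. Contrasts were mutant minus control in each of the 4 cell populations, donor minus host in each compartment, leptomeninges minus parenchyma in each origin (averaged over genotypes), and a pair of differences between genotype effects, 1 for donor minus host microglia and 1 for leptomeningeal minus parenchymal donor cells. Fold changes are log2 values ± standard error (SE), and levels are means ± standard deviation (SD) of CPM.

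Of 35 gene lists written in advance, covering macrophage states, pathways and marker genes of other cell types, 33 had the minimum of 5 tested members. Each was tested with limma's camera at its preset inter-gene correlation of 0.01, BH-adjusted over the 33 lists, and again with a correlation estimated from the data. Member counts are given over all genes tested and adjusted over the list alone. A list's share of UMIs is the sum of its members' counts over the library total. The genes named were chosen by a rule that was fixed in advance. It took the 10 largest differences in each direction with an adjusted p under 0.05, a mean of at least 10 CPM over all libraries compared and libraries that did not overlap between the sides (not asked of the differences between genotype effects), up to 4 members per list with the smallest adjusted p, and a fixed set of genes that included Dnmt3a and microglial and macrophage markers. Any other gene is said to be chosen after its values were seen.

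Alternatives chosen before the data were examined were DESeq2's size factors in the same edgeR test, no low-count filter, DESeq2's Wald test, limma's voom with sample quality weights, the groups of a contrast fitted alone, replicate numbers as a block, leaving out each library in turn, and the estimated correlation for lists. Alternatives chosen after seeing the data left out both donor microglia libraries that stood apart on principal components 4 and 5. These were control library 1 and mutant library 4, and control library 2 was kept. Further ones used the expression of the astrocyte and neuron lists, or of the neutrophil list, as a covariate. The rest scaled libraries to the complement and phagocytosis list, or kept only genes seen in a reference population. An alternative without libraries under 326930 UMIs, a set share of the median total, was not run, since 0 libraries were below it. Log2 CPM with a prior count of 2 entered principal components, the check of replicate numbers, the covariates from lists and the exact permutation tests. The scaling to the complement and phagocytosis list added a pseudocount to its counts. The replicate block was the number alone for mutant minus control, which ties control to mutant libraries of different chimeras. For the other contrasts it was genotype and number together.

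The tests were tested on simulated data with the depths of each genotype comparison and 200 changed genes. At a 2-fold change edgeR recovered 62% of the changed genes in donor microglia, 88% in host microglia, 80% in donor leptomeningeal cells and 43% in host leptomeningeal cells, and at a 4-fold change 99%, 100%, 100% and 98%. False calls numbered 5, 10, 10 and 3. Changed genes were drawn from those at 10 CPM or more in the pooled counts. Apart from the changes, a gene had the same expected share of UMIs and the same dispersion in every group. Recovery of genes below that level, or with structure within the real groups, was not simulated. A shifted list was called in every simulation, and 0 of the other 33 lists were called. The simulated genes varied independently and the other lists were random genes, so this does not test list calls where genes are correlated. Among other splits of the real donor microglia libraries, up to 19 lists were called. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table (1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.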

Results

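The data are UMI counts of 28 libraries of macrophages sorted from irradiated Cx3cr1-gfp/+ mice, 16 weeks after they received control or mutant human DNMT3A marrow. Donor microglia had 589463 ± 88230 UMIs in control and 861240 ± 251596 in mutant chimeras (SD, n = 4 each). Host microglia had 2314237 ± 403529 and 1911442 ± 434861, and donor leptomeningeal cells 2551782 ± 417608 and 2192088 ± 511309 (n = 4 each). Host leptomeningeal cells had 1069950 ± 271592 in control and 1235586 ± 338773 in mutant chimeras (n = 2 each). The first principal component held 44.5% of the variance and separated host microglia from donor leptomeningeal cells. The second held 26.9% and set donor microglia apart from the other populations.

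**Figure D1:**
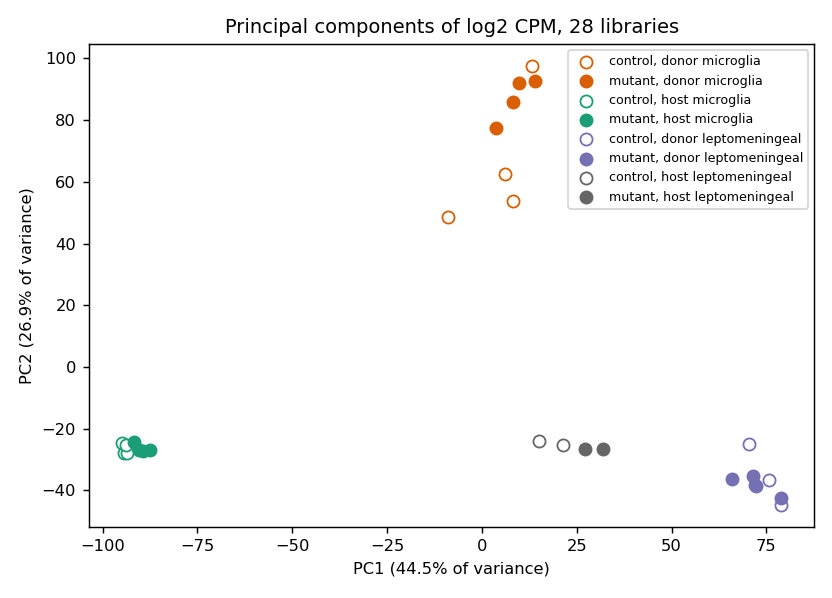
First against second principal component of log2 CPM, with 1 point per library, a colour per cell population, open points for control and filled points for mutant chimeras. Libraries grouped by population, and the components held 44.5% and 26.9% of the variance.

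Mutant against control donor microglia (n = 4 each) asked what the recombined allele changes in marrow-derived cells of the parenchyma. Spint1, which encodes a membrane-bound inhibitor of serine proteases (mm10 chromosome 2, 119237362 to 119249527), rose by 2.63 ± 0.28 on the log2 scale (adjusted p = 2.38e-08), to 71.3 ± 15.4 CPM from 11.7 ± 4.17. Commd10, of a gene family with roles in endosomal sorting and NF-kB control (chromosome 18, 46958816 to 47234284), rose by 1.93 ± 0.23 (adjusted p = 2.62e-07), to 84.0 ± 10.1 CPM from 22.5 ± 10.3. Apobec3, a cytidine deaminase that restricts retroviruses (chromosome 15, 79891659 to 79915906), fell by 0.74 ± 0.13 (adjusted p = 0.00443), from 204.7 ± 35.04 to 121 ± 19.06 CPM. Gatm, the first enzyme of creatine synthesis (chromosome 2, 122594467 to 122611303), fell by 0.63 ± 0.13 (adjusted p = 0.0207), from 571 ± 34.5 to 369.5 ± 27.0 CPM. Per1 of the circadian clock rose by 1.23 ± 0.20 (adjusted p = 0.00119), and Tsc22d3, a target of glucocorticoids, by 0.84 ± 0.17 (adjusted p = 0.0191). The ribosomal protein genes Rpl38 and Rps6 rose by 0.78 and 0.67, and Id2, a repressor of transcription factors, by 0.60. Hps6, which serves lysosome-related organelles, and the Golgi mannosidase Man1a fell by 1.82 and 1.00 (SE 0.37 and 0.21). The targeted gene's mouse copy, Dnmt3a, did not pass (-0.09 ± 0.18, adjusted p = 0.905), at 69.6 ± 15.9 CPM in control and 67.2 ± 8.56 in mutant cells. These counts do not measure the human allele separately, and whether its transcripts add to them was not tested. Dnmt1, Tet2, Apoe, Cd74 and Tmem119 did not pass either, with folds of -0.03, -0.09, -0.31, 0.23 and -0.12. In all, 11 of 12327 genes passed, 7 higher and 4 lower, with 3 and 2 of them past a 2-fold change, and 1253 genes had an unadjusted p under 0.05. Spint1 and Commd10 passed under every alternative run, and Per1 under all but the astrocyte and neuron covariate. There Per1 had a fold of 1.115 ± 0.25 (adjusted p = 0.117, with 1.3e-05 to 0.117 over the alternatives), and the larger SE and slightly smaller fold ended the call. Of the 11 genes, 3, 11, 7 and 5 passed without control library 1, 2, 3 or 4 and 7, 6, 7 and 11 without mutant library 1, 2, 3 or 4, when edgeR called 3, 496, 9 and 6 and 14, 7, 7 and 19 genes, against 81 with DESeq2 and 124 with voom.

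Among the gene lists in donor microglia, neutrophil genes had a median of -2.06 (0 of 18 passed, 12 lower adjusted over the list alone; adjusted p = 4.16e-14, and adjusted p = 0.171 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.24, with 1 of 39 higher and 20 higher adjusted over the list alone (adjusted p = 3.7e-13, and adjusted p = 0.177 with an estimated correlation). Genes of oxidative phosphorylation had a median of 0.25, with 0 of 59 passing and 9 higher adjusted over the list alone (adjusted p = 4.16e-14, and adjusted p = 0.263 with an estimated correlation). Neuron and astrocyte genes had medians of 0.83 and 0.69 with 0 of 17 passing each (adjusted p = 9.47e-10 and 1.84e-08, and adjusted p = 0.174 and 0.263 with an estimated correlation). Dendritic cell genes had a median of 1.26, with 0 of 12 passing and 1 higher adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.144 with an estimated correlation). Immediate early genes had a median of 0.26, with 4 of 26 higher and 1 lower adjusted over the list alone (adjusted p = 7.87e-06, and adjusted p = 0.263 with an estimated correlation), and cell cycle genes of -0.52 (adjusted p = 6.34e-06, and adjusted p = 0.404 with an estimated correlation). With the astrocyte and neuron lists as a covariate, 8 of the 13 lists called lost the call. Among them were genes of oxidative phosphorylation, the cell cycle and monocytes (adjusted p = 0.219, 0.107 and 0.107, with 3.25e-19 to 0.263, 8.55e-07 to 0.404 and 1.28e-05 to 0.404 over the alternatives). Neuron, astrocyte and oligodendrocyte genes lost it too (adjusted p = 0.475, 0.562 and 0.284, with 1.1e-22 to 0.475, 7e-35 to 0.562 and 1.12e-07 to 0.392). So did homeostatic microglial genes and genes of marrow-derived microglia (adjusted p = 0.682 and 0.861, with 9.62e-05 to 0.682 and 0.00405 to 0.861), which had medians of -0.165 and -0.17 with 0 of 26 and 0 of 22 passing (adjusted p = 0.00106 and 0.0331 without the covariate, and adjusted p = 0.548 each with an estimated correlation). In all, camera called 13 of 33 lists at its preset correlation, 8 higher and 5 lower, and 0 with an estimated correlation. Astrocyte genes took 0.145%, 0.178% and 0.245% of UMIs in control libraries 1, 3 and 4, against 0.725% in control library 2 and 0.401% to 0.651% in mutant libraries. Mitochondrially encoded genes took 1.579%, 1.868% and 2.461% in control libraries 1, 3 and 4, against 4.724% in control library 2 and 2.509% to 4.127% in mutant libraries. Neutrophil genes took 0.1457% and 0.3167% in control libraries 1 and 2, 0.869% and 1.12% in control libraries 3 and 4, and 0.112% to 0.196% in mutant libraries.

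Mutant against control donor leptomeningeal cells (n = 4 each) put the same question to marrow-derived cells of the brain's surface. Commd10 rose by 1.97 ± 0.18 (adjusted p = 1.27e-10), to 69.7 ± 13.6 CPM from 17.6 ± 2.29. Eps8l1, which links receptors to actin remodelling (chromosome 7), rose by 1.94 ± 0.27 (adjusted p = 1.38e-05), to 23.96 ± 5.54 CPM from 6.37 ± 1.90. Slc15a2, a peptide transporter (chromosome 16), rose by 2.27 ± 0.39 (adjusted p = 0.014), and Spint1, outside the naming rule here and chosen after its values were seen, by 2.89 ± 0.36 (adjusted p = 1.61e-06), to 12.02 ± 2.72 CPM from 1.73 ± 1.65. Apobec3 fell by 0.66 ± 0.12 (adjusted p = 0.00335), from 178.2 ± 1.18 to 112.6 ± 7.23 CPM, and Gatm by 0.63 ± 0.13 (adjusted p = 0.0246). These were all 6 genes that passed, 4 higher and 2 lower, with 597 at an unadjusted p under 0.05 and 11 passing with voom. Mouse Dnmt3a (0.04 ± 0.17), Cd74 (0.27 ± 0.17) and Mrc1 (-0.03 ± 0.13) did not pass. Commd10 and Spint1 were higher, and Apobec3 and Gatm lower, in both donor populations. There 0.00227 and 0.000649 shared genes would be met if the calls were independent (one-sided Fisher's exact p = 1.66e-06 and 7.9e-08). Both comparisons set the same donor lines against each other, so their calls need not be independent and the overlap is not a separate replication. In donor microglia Apobec3 and Gatm missed the threshold with these groups fitted alone (adjusted p = 0.152 and 0.102) and with the astrocyte and neuron covariate (adjusted p = 0.514 and 0.269). Both also missed it there without control library 1 (adjusted p = 0.0744 and 0.101) or mutant library 2 (adjusted p = 0.0602 and 0.0981). Across all genes, which are not independent replicates, the genotype folds of both donor populations had a correlation of -0.0256. Ribosomal protein genes had a median of 0.17 with 0 of 39 passing (adjusted p = 1.01e-12, and adjusted p = 0.247 with an estimated correlation), and cell cycle genes of -0.42 with 0 of 31 passing (adjusted p = 1.08e-08, and adjusted p = 0.306 with an estimated correlation). Cell cycle genes took 0.107%, 0.2153%, 0.1431% and 0.1652% of UMIs in control libraries 1 to 4, where neutrophil genes took 5.665%, 9.971%, 6.037% and 7.336%. In mutant libraries 1 to 4 cell cycle genes took 0.1123%, 0.09028%, 0.1649% and 0.1138%, and neutrophil genes 5.675%, 3.71%, 8.563% and 5.577%. With the neutrophil list as a covariate, cell cycle and ribosomal protein genes were still called (adjusted p = 1.52e-06 and 3.15e-11, with 1.96e-19 to 0.306 and 1.18e-14 to 0.247 over the alternatives). Of the 10 lists called, homeostatic microglial and border macrophage genes no longer were (adjusted p = 0.196 and 0.274, with 7.74e-06 to 0.992 and 0.000165 to 0.992 over the alternatives). MHC class II genes had a median of 0.19 (adjusted p = 4.79e-05, and adjusted p = 0.247 with an estimated correlation). In all, 10 of 33 lists were called, 7 higher and 3 lower, and 0 with an estimated correlation, and counts adjusted over the list alone exceeded those over all genes by at most 1 member. Slc15a2 missed the threshold without control library 1, 2 or 4 or mutant library 4 (adjusted p = 0.105, 0.124, 0.0651 and 0.067, and 9.2e-06 to 0.124 over all alternatives), and Gatm without control library 1 or 4 or mutant library 1, 3 or 4 (adjusted p = 0.149, 0.288, 0.0676, 0.257 and 0.153, and 0.00219 to 0.288 over all alternatives).

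**Figure D2:**
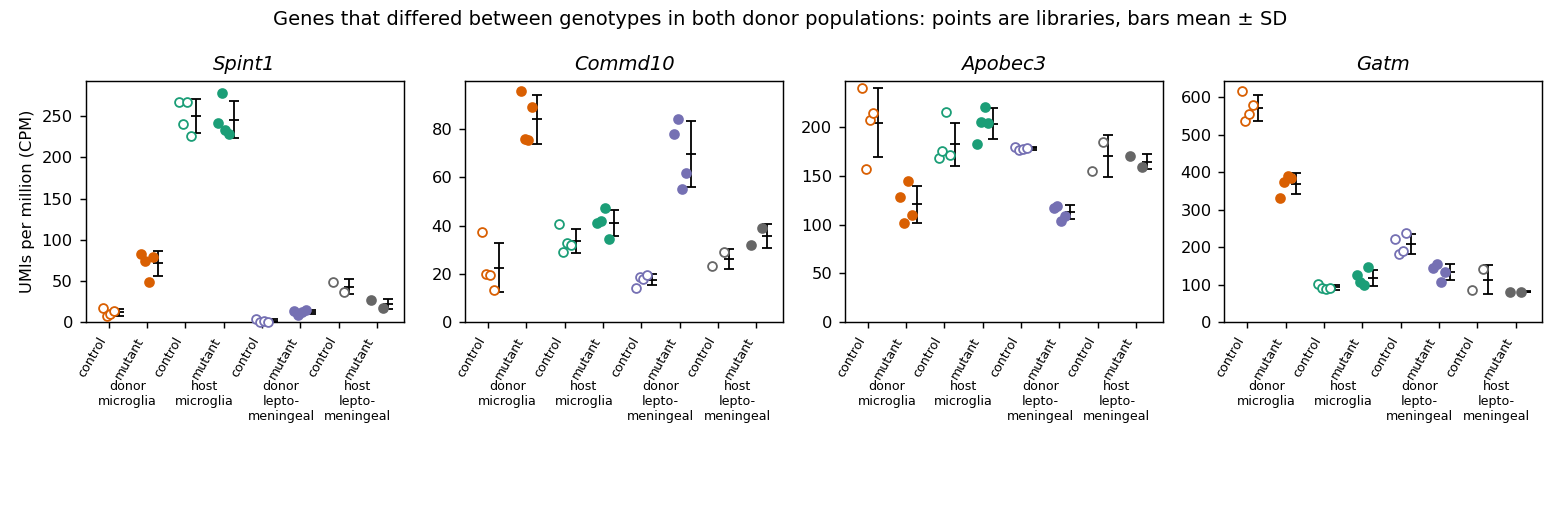
CPM of Spint1, Commd10, Apobec3 and Gatm in the 8 groups, with 1 point per library, open for control and filled for mutant chimeras, and bars for the mean ± SD. Commd10 was at 84.0 ± 10.1 CPM in mutant and 22.5 ± 10.3 in control donor microglia, and at 41.1 ± 5.35 and 33.6 ± 4.87 in host microglia.

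Host microglia of mutant against control chimeras (n = 4 each) carry no marrow allele, so this comparison asked what changes around the donor cells. The MHC class II genes H2-Ab1 and H2-Eb1 rose by 1.04 ± 0.17 and 1.14 ± 0.20 (adjusted p = 0.019 and 0.0258), and Cd74, the chaperone of class II molecules, by 0.96 ± 0.17 (adjusted p = 0.0258). H2-Ab1 reached 487.8 ± 152.1 CPM from 237.7 ± 48.8, H2-Eb1 334.3 ± 102.6 from 151.1 ± 41.1 and Cd74 462.9 ± 143.7 from 238.4 ± 36.2. Mgl2, a C-type lectin of macrophages and dendritic cells, rose by 1.17 ± 0.24 (adjusted p = 0.0377), to 15.1 ± 5.10 CPM from 6.63 ± 2.39. Ddit4, an inhibitor of mTOR signalling, rose by 0.87 ± 0.17 (adjusted p = 0.0271), and the transcription factor Klf2 by 0.70 ± 0.15 (adjusted p = 0.0377). Gm45640, a predicted gene, fell by 0.85 ± 0.17 (adjusted p = 0.0258). The chemokine receptor Cxcr4, outside the naming rule and chosen after its values were seen, rose by 2.15 ± 0.46 (adjusted p = 0.0464), to 4.35 ± 1.39 CPM. The MHC class II list had a median of 0.49, with 3 of 10 members higher and 4 adjusted over the list alone, and was called also with an estimated correlation (adjusted p = 2.75e-14 and 0.0099). T and NK cell genes had a median of 0.92, with 0 of 20 passing and 4 higher adjusted over the list alone (adjusted p = 3.25e-09, and 0.0391 with an estimated correlation). Both lists passed, at the preset correlation, without each library in turn. Genes of marrow-derived microglia had a median of 0.19, with 0 of 22 passing and 5 higher adjusted over the list alone (adjusted p = 0.00321, and adjusted p = 0.921 with an estimated correlation). H2-Aa (1.17 ± 0.24, adjusted p = 0.0909), Apoe (0.575 ± 0.14, adjusted p = 0.165), P2ry12, Tmem119, Cx3cr1 and mouse Dnmt3a (adjusted p = 1 each) did not pass in the main test. H2-Aa passed with DESeq2 (adjusted p = 0.00018) and with replicate numbers as a block (adjusted p = 0.00541). It also passed without control library 3 or mutant library 1 (adjusted p = 0.0129 and 0.00229, with 0.00018 to 0.871 over the alternatives). Apoe passed with DESeq2 (adjusted p = 0.0494, with 0.0494 to 0.869 over the alternatives). In all, 8 genes passed, 7 higher and 1 lower, and 463 had an unadjusted p under 0.05. Camera called 4 of 33 lists, all higher. Of the 8 genes, 0, 0, 5 and 3 passed without control library 1, 2, 3 or 4 and 6, 0, 0 and 0 without mutant library 1, 2, 3 or 4, and edgeR called 0 genes with these groups fitted alone, while DESeq2 called 15 and voom 5.

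**Figure D3:**
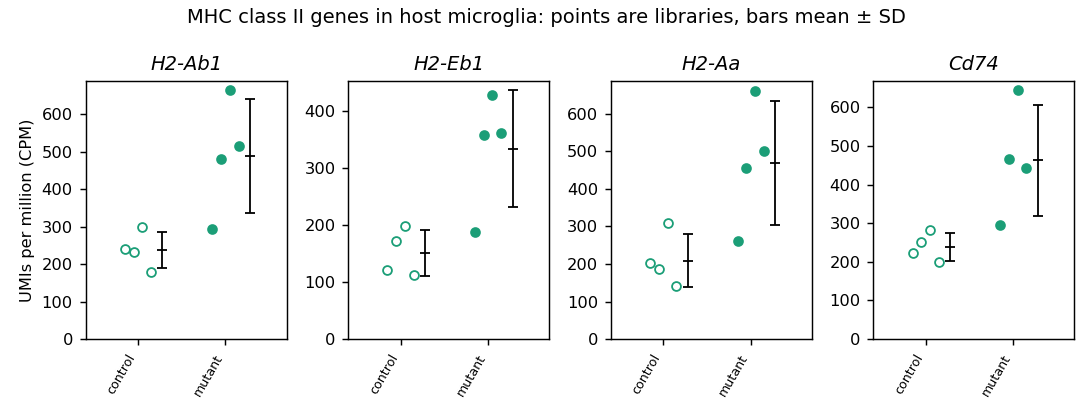
CPM of H2-Ab1, H2-Eb1, H2-Aa and Cd74 in host microglia, with 1 point per library and bars for the mean ± SD. H2-Ab1 lay at 179.5 to 298.8 CPM in control and 293.8 to 663.8 CPM in mutant chimeras. H2-Aa did not pass the threshold in the main test, but passed with DESeq2 and with replicate numbers as a block.

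Host leptomeningeal macrophages of mutant against control chimeras (n = 2 each) addressed the same question at the brain's surface. Homeostatic microglial genes had a median of -0.60, with 0 of 26 passing and 8 lower adjusted over the list alone (adjusted p = 1.18e-18, and adjusted p = 0.226 with an estimated correlation). Among them Sall1, a transcription factor of microglial identity, had a fold of -1.48 ± 0.40 (adjusted p = 0.298), at 15.0 ± 5.03 CPM in mutant and 39.4 ± 12.9 in control chimeras. Tmem119 (-0.91 ± 0.30) did not pass either. Both passed with these groups fitted alone (adjusted p = 0.0302 and 0.0316, with 0.00361 to 1 and 0.0316 to 1 over the alternatives). Border macrophage genes had a median of 0.30, with 0 of 23 passing and 0 adjusted over the list alone (adjusted p = 0.00138, and adjusted p = 0.556 with an estimated correlation). The adjusted p was 0.382 without control library 1 (3.3e-05 to 0.556 over the alternatives). Homeostatic genes took 5.598% and 4.581% of UMIs in control and 3.979% and 3.395% in mutant libraries 1 and 2. Border macrophage genes took 1.613% and 1.921% in control and 1.973% and 2.229% in mutant libraries. Type I interferon genes had a median of 0.33 with 0 of 43 passing (adjusted p = 0.000124, and adjusted p = 0.732 with an estimated correlation), and the adjusted p was 0.748 without mutant library 1 (3.36e-11 to 0.748 over the alternatives). By gene, edgeR called 0, with 666 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0568, for Cdk5r1 (-1.87 ± 0.36) and Slc44a2 (-1.17 ± 0.24), which were chosen after their values were seen. Both passed with DESeq2's test, with its size factors in edgeR, without a low-count filter and with these groups fitted alone, and missed the threshold with voom (adjusted p = 0.00636 to 0.583 for Cdk5r1 and 0.00361 to 0.583 for Slc44a2 over the alternatives). Of the 4 fits with 1 library left out, Cdk5r1 passed in that without control library 2 and Slc44a2 in 0, and both were at 0.583 without mutant library 2. DESeq2 called 25, 2 higher and 23 lower, among them Sall1 (adjusted p = 0.00361, and 0.00361 to 1 over the alternatives), and voom called 0. The edgeR count was 4 without control library 2, 5 without mutant library 1 and 1 without mutant library 2. Lipid efflux genes had a median of 0.07 but a mean of -0.26 and a lower call (adjusted p = 0.0417, and adjusted p = 0.235 with an estimated correlation), lost without control or mutant library 2 (adjusted p = 0.143 and 0.321). Camera called 9 of 33 lists, 6 higher and 3 lower, and 0 with an estimated correlation.

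The difference between genotype effects in donor and host microglia tested which genes depend on the cell carrying the allele. Spint1 (2.66 ± 0.31, adjusted p = 7.07e-07) and Commd10 (1.64 ± 0.28, adjusted p = 0.00364) had a larger genotype fold in donor than in host microglia. Gatm (-0.98 ± 0.18, adjusted p = 0.0125) and Apobec3 (-0.89 ± 0.17, adjusted p = 0.0194) had a lower one. These 4 genes were all that passed, against 745 at an unadjusted p under 0.05 and 14 passing with DESeq2. In host microglia their genotype folds were -0.03 ± 0.13 for Spint1, 0.29 ± 0.16 for Commd10, 0.35 ± 0.13 for Gatm and 0.155 ± 0.11 for Apobec3 (adjusted p = 1 each). The class II genes H2-Ab1 (-0.90 ± 0.24, adjusted p = 0.371) and Cd74 (-0.73 ± 0.24, adjusted p = 0.652) were not shown to differ between host and donor microglia in the main test. With replicate numbers as a block, H2-Ab1 (-0.885, adjusted p = 0.032) and H2-Aa (-0.999, adjusted p = 0.0445) passed. H2-Ab1 also passed without mutant host library 1 (-1.076, adjusted p = 0.00604, with 0.00604 to 0.795 over the alternatives). As a list, MHC class II genes had a median of -0.25, with 0 of 10 passing and 4 lower adjusted over the list alone (adjusted p = 0.00209, and adjusted p = 0.377 with an estimated correlation). Gatm and Apobec3 depended on single libraries, as the count was 2 without control donor library 1, control host library 4 or mutant donor library 1 or 2, and 63 without control donor library 2. Apobec3 also missed the threshold without control donor library 3 or 4, control host library 1, mutant donor library 4 or mutant host library 2 or 3. It missed it with these groups fitted alone too (adjusted p = 0.126), and Gatm also missed it without control host library 3 or mutant host library 4.

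Between donor leptomeningeal cells and donor microglia, the genotype effects differed in 0 genes by edgeR, with 787 at an unadjusted p under 0.05 and a smallest adjusted p of 0.155. DESeq2 called 2 and voom 1, and edgeR called 134 (9 higher and 125 lower) without control donor microglia library 2. The differences were 0.26 ± 0.45 for Spint1, 0.035 ± 0.29 for Commd10, -0.004 ± 0.17 for Gatm, 0.07 ± 0.18 for Apobec3, 0.66 ± 0.45 for Eps8l1 and 0.08 ± 0.93 for Slc15a2. Neuron genes had a median of -1.28, with 0 of 17 passing and 5 lower adjusted over the list alone (adjusted p = 1.84e-12, and adjusted p = 0.213 with an estimated correlation). Neutrophil genes had a median of 1.71, with 0 of 18 passing and 7 higher adjusted over the list alone (adjusted p = 3.41e-10, and adjusted p = 0.458 with an estimated correlation). Camera called 11 of 33 lists in this comparison and 11 in that between donor and host microglia, and 0 with an estimated correlation in both.

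Donor against host microglia (n = 8 each) asked how marrow-derived cells differ from resident ones in the parenchyma. Apoe, which encodes a lipid carrier, rose by 4.71 ± 0.11 (adjusted p = 3.5e-30), to 93940 ± 15520 CPM from 3633 ± 845.3. The marrow-derived microglial markers Ms4a7 and Clec12a rose by 5.43 ± 0.15 and 5.23 ± 0.14, and the protease gene Ace by 6.20 ± 0.26. Lyz2 and Axl, a receptor for dying cells, were higher by 3.61 and 3.31, the border macrophage genes Mrc1 and Pf4 by 3.66 and 3.94, and the monocyte chemokine receptor Ccr2 by 3.12. The transcription factors Sall1 and Sall3 fell by 4.14 ± 0.18 and 4.17 ± 0.21, P2ry12, a purine receptor, by 3.11 ± 0.23, and Tmem119 by 2.05. Genes of marrow-derived microglia had 21 of 22 members higher and 1 lower (median 2.76, the same counts adjusted over the list alone; adjusted p = 6.31e-33, and 0.000563 with an estimated correlation). Homeostatic microglial genes had 26 of 26 lower (median -2.15, 26 adjusted over the list alone; adjusted p = 6.57e-35, and 0.00864 with an estimated correlation). MHC class II genes had 8 of 10 higher and 2 lower (median 2.44; adjusted p = 8.25e-09, and 0.0483 with an estimated correlation), with Cd74 up by 4.23 ± 0.14. Mouse Dnmt3a was lower in donor than in host microglia, by -0.61 ± 0.11 (adjusted p = 4.73e-06), at 68.4 ± 11.9 and 104 ± 6.31 CPM.

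In the same comparison, astrocyte genes were higher in 17 of 17 members (median 7.31; adjusted p = 4.83e-15, and adjusted p = 0.108 with an estimated correlation) and neuron genes in 16 of 17 (median 5.04; adjusted p = 2.05e-10, and adjusted p = 0.114 with an estimated correlation). The astrocyte glutamate transporter Slc1a2 was at 431.3 ± 242.8 CPM in donor and 0.935 ± 0.925 in host microglia, and the neuronal gene Rbfox3 at 158.8 ± 54.0 and 4.61 ± 1.44. Mitochondrially encoded genes took 2.658 ± 1.425% and 3.422 ± 0.7365% of UMIs in control and mutant donor microglia, against 0.2406 ± 0.1033% and 0.2188 ± 0.0858% in host microglia. Ttr, made by the choroid plexus, was at 24280 ± 6044 and 72.3 ± 49.6 CPM (8.45 ± 0.93, adjusted p = 6.5e-08). In all, 7448 genes passed, 4084 higher and 3364 lower, with 2800 and 961 of them past a 2-fold change. Camera called 20 of 33 lists, 17 higher and 3 lower. Counts adjusted over the list alone differed from those over all genes by at most 2 members per list. Scaled to the complement and phagocytosis list, the share of higher genes rose from 54.8% to 68.3% and the median of all genes moved to 0.224. Cx3cr1, of which host cells carry 1 copy replaced by GFP, had a fold of -0.37 ± 0.14 (adjusted p = 0.0261), but the adjusted p was 0.069 with DESeq2's size factors, 0.167 with these groups fitted alone, and 0.205 with that scaling. It was 0.0529 without control donor library 1, 0.0658 without control donor library 2, 0.0732 and 0.0592 without mutant donor libraries 2 and 3, and 0.062 without mutant host library 3, with 1.04e-05 to 0.205 over the alternatives.

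**Figure D4:**
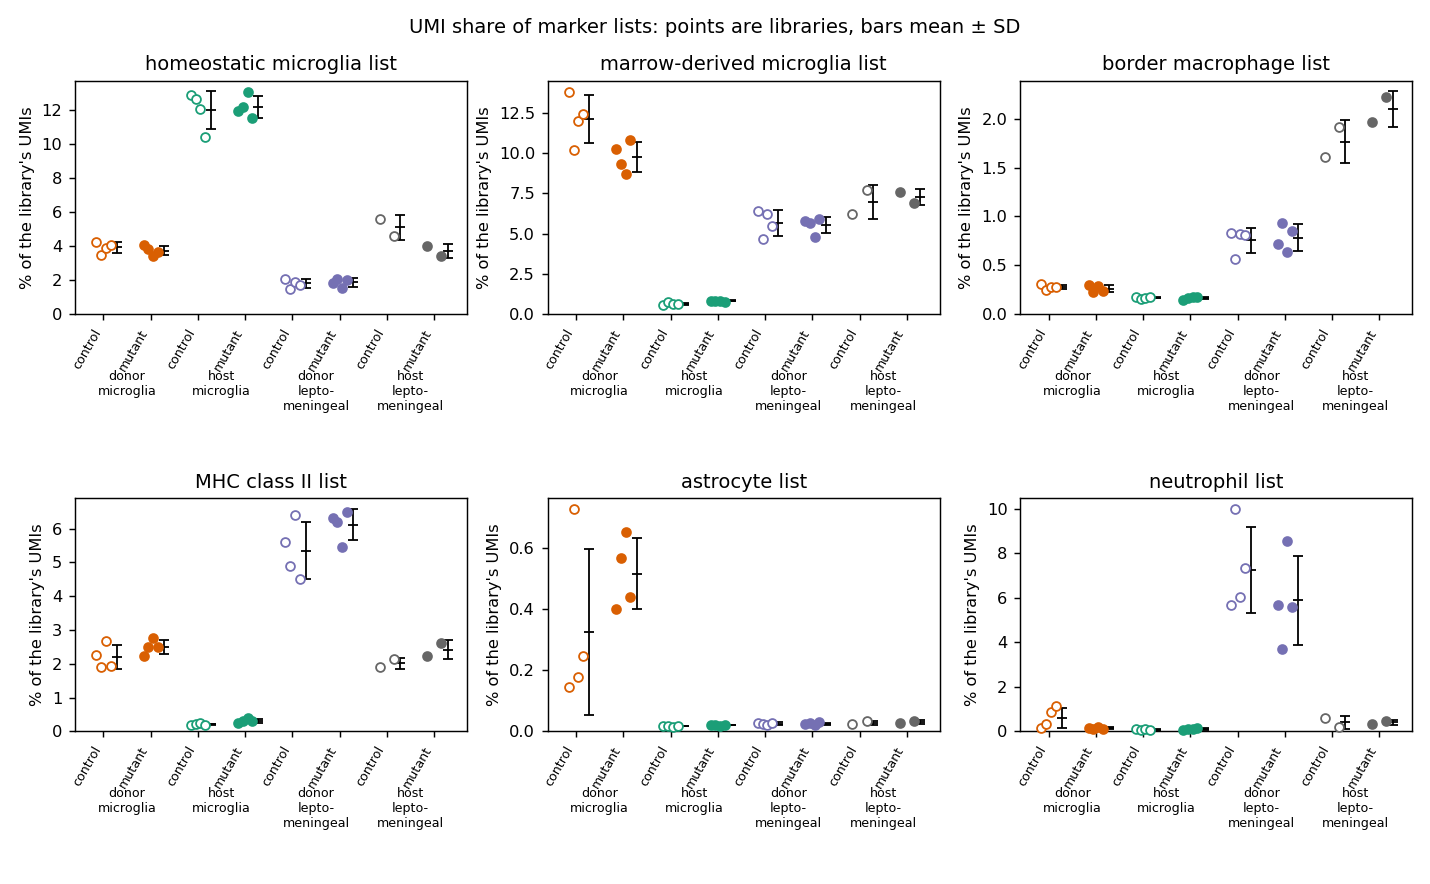
Percent of UMIs taken by 6 gene lists, with 1 point per library, open for control and filled for mutant chimeras, and bars for the mean ± SD. Homeostatic genes took 12.2 ± 0.663% of UMIs in mutant host and 3.72 ± 0.263% in mutant donor microglia, and the astrocyte list took more than 0.1% in donor microglia alone.

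Donor against host leptomeningeal cells (n = 8 and 4) asked the same at the brain's surface. Border macrophage genes were lower in 21 of 23 members and higher in 1 (median -1.18, the same counts adjusted over the list alone; adjusted p = 6.6e-23, and 0.0019 with an estimated correlation). Among them Cd209b, a lectin, fell by 4.03 ± 0.18, from 167 ± 37.4 to 10.01 ± 3.34 CPM, Mrc1, the mannose receptor, by 1.26 ± 0.11 and Pf4 by 1.07 ± 0.14. The phosphatidylserine receptor Timd4 fell by 5.14 ± 0.29, and homeostatic genes were lower in 25 of 26 members (median -1.97; adjusted p = 2.32e-50, and 0.0019 with an estimated correlation). Monocyte genes were higher in 18 of 18 members (median 2.88; adjusted p = 2.18e-20, and 0.00528 with an estimated correlation), with Ccr2 up by 2.05 ± 0.23 and Plac8 by 2.90 ± 0.24. MHC class II genes were higher in 10 of 10 (median 1.62; adjusted p = 7.08e-18, and 0.0019 with an estimated correlation), Cd74 by 1.41 ± 0.16 and H2-Aa by 1.71 ± 0.22. Cell cycle genes were higher in 30 of 31 members and 31 adjusted over the list alone (median 2.61; adjusted p = 1.61e-20, and 0.0321 with an estimated correlation), with the topoisomerase gene Top2a at 112.3 ± 40.4 and 9.54 ± 2.73 CPM. Lysosomal genes were lower in 22 of 32 and higher in 1 (median -0.56; adjusted p = 1.35e-12, and 0.0279 with an estimated correlation), with the cathepsin genes Ctsd and Ctsl down by -1.585 ± 0.11 and -1.56 ± 0.11. Neutrophil genes were higher in 17 of 18 (median 4.27, adjusted p = 6.68e-12, and adjusted p = 0.0735 with an estimated correlation). They took 7.25 ± 1.95% of UMIs in control and 5.88 ± 2.00% in mutant donor cells, against 0.2046% to 0.6097% in host libraries. Donor cells were sorted without GFP and host cells with it, so the mix of cells can differ between them. Whether other cells in the donor gate account for the folds of the other lists was not tested. The neutrophil protease gene Elane had the largest fold, 9.42 ± 1.68 (adjusted p = 0.000162, and 0.105 with voom, with 4.42e-08 to 0.105 over the alternatives). In all, 3718 genes passed, 2082 higher and 1636 lower. Camera called 16 of 33 lists, 10 higher and 6 lower, with at most 2 members per list called differently when adjusted over the list alone. Scaled to the complement and phagocytosis list, 82% rather than 56% were higher, the median of all genes moved to 0.303, and Apoe (-0.46 ± 0.12) and Dnmt3a (-0.55 ± 0.15) no longer passed (adjusted p = 0.238 and 0.263, with 0.000319 to 0.238 and 0.000962 to 0.263 over the alternatives). Dnmt3a also missed the threshold without control host library 1 (adjusted p = 0.0641).

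Donor leptomeningeal cells against donor microglia (n = 8 each) asked how marrow-derived cells differ with their place. Border macrophage genes were higher in 21 of 23 members and lower in 1 (median 3.57; adjusted p = 1.25e-18, and 0.0368 with an estimated correlation). The carbonyl reductase gene Cbr2 rose by 4.89 ± 0.17, to 1058 ± 237.7 CPM from 35.6 ± 8.18, Mgl2 by 3.83 ± 0.12, Pf4 by 2.21 ± 0.13 and Mrc1 by 1.36 ± 0.10. MHC class II genes were higher in 10 of 10 (median 1.515; adjusted p = 4.27e-08, and 0.0437 with an estimated correlation), with H2-Ab1 at 20900 ± 2969 and 5699 ± 697.5 CPM. Monocyte genes were higher in 16 of 18 and lower in 2 (median 3.72; adjusted p = 5.3e-13, and 0.0437 with an estimated correlation), with Ccr2 up by 2.82 ± 0.20 and the chemokine genes Ccl2 and Ccl7 by 2.97 ± 0.15 and 3.58 ± 0.17. Dendritic cell genes were higher in 10 of 12 and lower in 1 (median 1.99; adjusted p = 0.000349, and 0.0437 with an estimated correlation), with Cd209a up by 3.28 ± 0.16. Ribosomal protein genes were higher in 35 of 39 and lower in 2 (median 0.90; adjusted p = 5.41e-19, and 0.0437 with an estimated correlation). Homeostatic genes were lower in 23 of 26 (median -1.59; adjusted p = 3.75e-13, and adjusted p = 0.0986 with an estimated correlation), with Tmem119 down by -2.79 ± 0.16. Apoe and Ms4a7 were lower at the surface by -1.225 ± 0.10 and -1.87 ± 0.12, Trem2, a lipid-sensing receptor, by -1.93 ± 0.10, and mouse Dnmt3a by -1.16 ± 0.12. Neutrophil genes were higher in 17 of 18 (adjusted p = 3.74e-07, and adjusted p = 0.16 with an estimated correlation), with the calcium-binding S100a9 at 26530 ± 7271 and 554 ± 611.6 CPM. Astrocyte and neuron genes were lower in 16 of 17 and 17 of 17 (adjusted p = 9.42e-10 and 9.9e-11, and adjusted p = 0.16 and 0.107 with an estimated correlation). In all, 7650 genes passed, 3754 higher and 3896 lower. Camera called 18 of 33 lists, 14 higher and 4 lower, with at most 1 member per list called differently when adjusted over the list alone. The share higher was 49.1%, and 36% with a median of all genes of -0.242 when scaled to the complement and phagocytosis list.

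Host leptomeningeal macrophages against host microglia (n = 4 and 8) put the same question to resident cells. Border macrophage genes were higher in 23 of 23 members (median 6.68; adjusted p = 3.68e-64, and 3.98e-05 with an estimated correlation). Mrc1 rose by 6.28 ± 0.13, to 1328 ± 259.8 CPM from 16.8 ± 2.78, Pf4 by 7.22 ± 0.17, to 3237 ± 376.9 from 22.3 ± 6.10, and Lyve1, the hyaluronan receptor, by 8.15 ± 0.39. The lectin gene Cd209f and the scavenger receptor Cd163 rose by 9.22 ± 0.34 and 8.38 ± 0.38. Homeostatic genes were lower in 24 of 26 (median -2.03; adjusted p = 5.61e-20, and 0.0261 with an estimated correlation), with Sall1 down by -3.60 ± 0.21 and P2ry12 by -2.06 ± 0.28. Genes of marrow-derived microglia were higher in 20 of 22 and lower in 2 (median 3.61; adjusted p = 4.13e-32, and 0.000298 with an estimated correlation), with Apoe up by 3.95 ± 0.12 and Ms4a7 by 4.54 ± 0.16. T and NK cell genes were higher in 19 of 20 (median 3.40; adjusted p = 3.98e-14, and 0.00982 with an estimated correlation), with Cd4 at 87.9 ± 19.11 and 1.14 ± 1.12 CPM. Immediate early genes were higher in 22 of 26 and lower in 2 (median 1.47; adjusted p = 3.98e-14, and 0.0261 with an estimated correlation), with Fos up by 2.62 ± 0.12 and Klf4 by 3.36 ± 0.11. Fibroblast and mural cell genes were higher in 10 of 11 (median 5.48; adjusted p = 3.63e-09, and 0.0149 with an estimated correlation), and Ptgds, a prostaglandin synthase gene of the meninges, was at 4255 ± 793.9 and 21.6 ± 3.28 CPM. Genes of TGF-beta signalling were lower in 9 of 16 and higher in 4 (median -0.63; adjusted p = 0.017, and 0.0358 with an estimated correlation), with the receptor gene Tgfbr1 down by -2.23 ± 0.19 and Smad3 by -2.03 ± 0.17. Mouse Dnmt3a was lower by -1.22 ± 0.14, at 44.3 ± 4.18 against 104 ± 6.31 CPM. In all, 6994 genes passed, 3832 higher and 3162 lower. Camera called 22 of 33 lists, 20 higher and 2 lower, with at most 5 members per list called differently when adjusted over the list alone. The share higher was 54.8%, and 37.1% with a median of all genes of -0.231 when scaled to the complement and phagocytosis list.

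**Figure D5:**
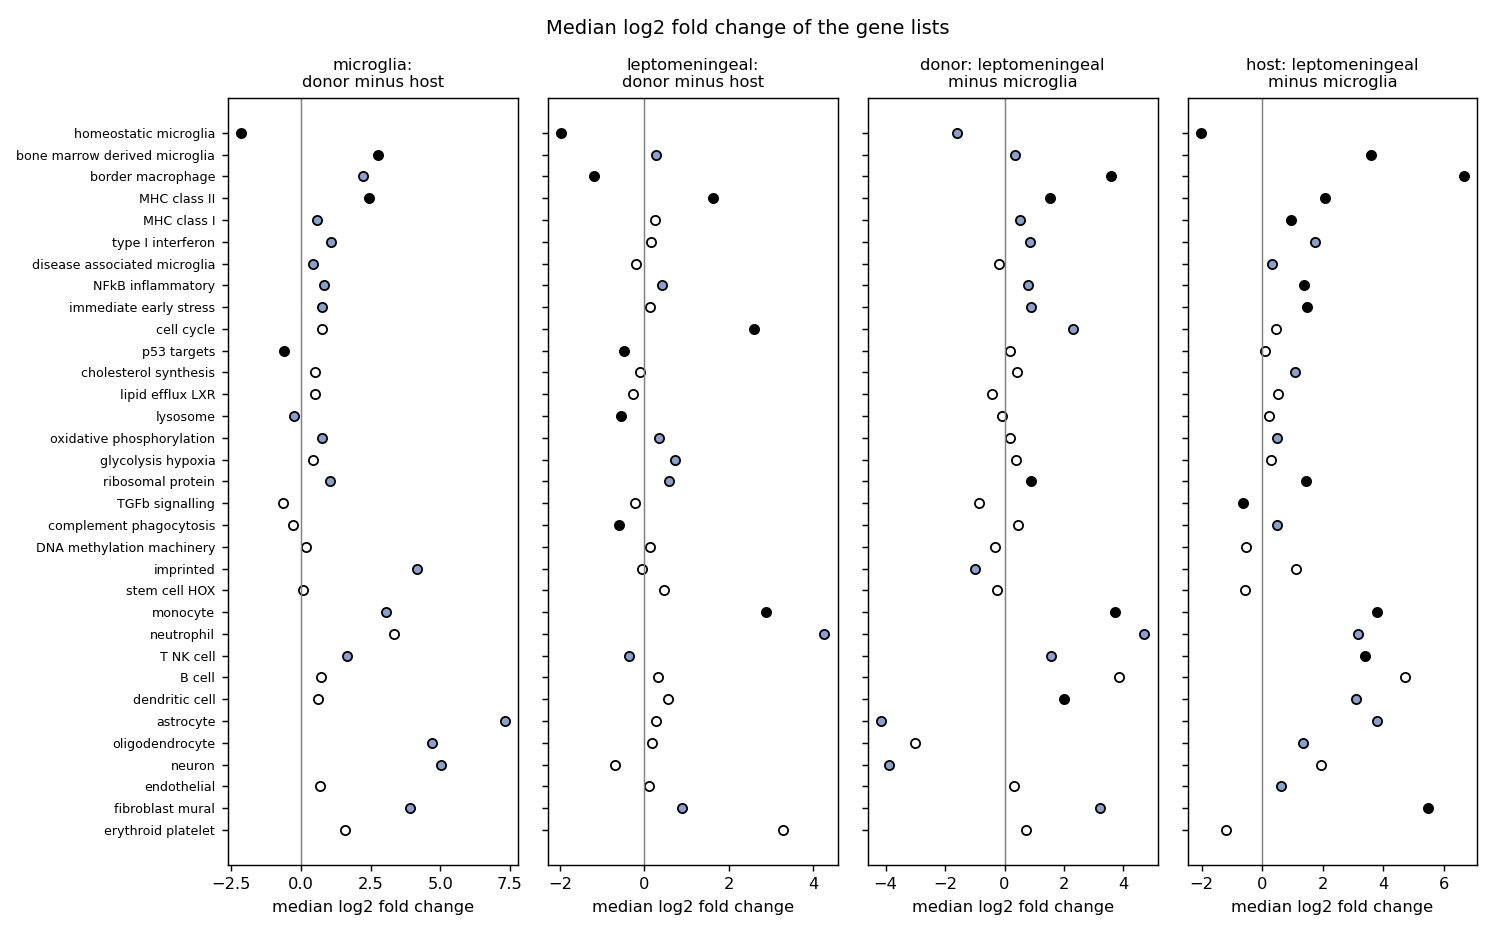
Median log2 fold change of 33 gene lists in the 4 comparisons of origin and compartment. Black points passed camera also with an estimated correlation (4, 8, 5 and 12 lists from left to right), blue points only at the preset correlation and white points at neither, and the homeostatic list lay below 0 in each panel.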

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

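Tests of host cells in the donor gate, of donor cells in the host gate, and of brain RNA in donor microglia were chosen after the results were seen.

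Spint1 and Commd10 were higher and Apobec3 and Gatm lower in mutant donor cells of both compartments, and tests of the difference between donor and host microglia gave 2.656 (SE 0.31) for Spint1, 1.641 (SE 0.28) for Commd10, -0.978 (SE 0.18) for Gatm and -0.891 (SE 0.17) for Apobec3. For donor microglia, host cells in the mutant donor gate are argued against. The 25.2% of host cells needed for Spint1 would raise homeostatic genes by a median of 0.789. Their observed median was -0.165 (SD 0.4), and 26 of 26 members lay below the fold that this share would give that member. Also, Commd10 at 84.0 CPM in mutant donor microglia exceeded its 37.4 CPM in host microglia. The share of host cells was not tested in the leptomeningeal donor gate. There Spint1 in mutant donor cells (12.02 CPM) lay below host cells of control and mutant chimeras (43.17 and 22.19 CPM). Commd10 (69.7 CPM) lay above them (26.15 and 35.56 CPM). A passenger region that differs between the donor lines may contribute for Spint1 and Gatm, which lie 3.36 Mb apart on chromosome 2. Within 5 Mb of either, 24 of 112 other genes had an unadjusted p under 0.05 in either donor comparison (21.4%), against 1701 of 12053 elsewhere (14.1%). The odds ratio was 1.66 (95% interval 1.01 to 2.64, two-sided Fisher's exact p = 0.0397). That test treats genes as independent, which genes of the same libraries are not, and it was not run in host cells. Both donor lines carried the floxed allele, so a region linked to that allele would not by itself separate them. A Cre transgene in or beside Commd10 cannot be told apart from the genotype, since every mutant donor library carries it: Commd10 had a fold of 0.294 ± 0.16 in host microglia, which lack it, and 0 of 9 neighbours within 1 Mb had an unadjusted p under 0.05 in both donor comparisons (smallest 0.0184 and 0.0682), but an insertion that acts on Commd10 alone would leave neighbours unchanged. The DNMT3A allele itself and a strain difference between the donor lines stay open, untested.

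MHC class II genes were higher in host microglia of mutant chimeras, which the marrow allele cannot act on directly. For donor microglia carried into the host gate, 38 abundant donor markers implied a median share of 1.58% (quartiles 0.605% and 2.7%). That lies below the 3.45% that Cd74, the lowest of the class II genes called, needs. But the markers include mitochondrial genes such as mt-Nd4 (-0.841%), which lower the median and may not measure donor cells. Apoe, Ms4a7 and Clec12a implied 1.77%, 0.747% and 2.02%, below the share needed, and Crip1 and Vim 7.9% and 4.88%, above it. Carry-over of donor microglia is therefore not excluded. Donor leptomeningeal cells may also contribute and cannot be told apart from a change in host cells. Their 190 markers implied 0.55% with an upper quartile of 1.33%, above the lowest share needed of 1.13%. T and NK cell genes, also called higher in this comparison, took 0.004805% to 0.007736% of UMIs in control and 0.007996% to 0.0111% in mutant host libraries. Other cell types in the host gate were not tested as a source. A response of host microglia to mutant donor cells stays open, untested, and the count of 8 genes called was reached by another of the 35 splits.

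Homeostatic genes were lower and brain-cell genes higher in donor than in host microglia. Dilution of microglial RNA alone is argued against, because it lowers every member alike, while the 26 folds ran from -4.85 to -0.37 with an SD of 1.22, 8.47 times their median SE of 0.144. RNA or cells of the brain and choroid plexus in the donor microglia gate may account for the rise of brain-cell genes: 42 of 46 members of the astrocyte, neuron and oligodendrocyte lists were higher in donor than in host microglia (17 of 17, 16 of 17 and 9 of 12), and 16 of 17, 17 of 17 and 8 of 12 were lower in donor leptomeningeal cells. The removal of myelin should limit them only in part, and a gate on cells without GFP does not exclude them. A difference of origin stays open for homeostatic genes, untested against other effects of irradiation.

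Other results stood out in plain ways, and chance alone picks out about 1 in 20 groups, against 5 of 144 groups of 4 libraries tested here. Mutant donor microglia library 4 had 487382 UMIs, and the other 3 had 937447 to 1013608. Apobec3 was at 215.5 CPM in control host microglia library 3 and at 168.1 to 175.6 in the others. Eps8l1 was at 36.1 CPM in mutant donor microglia library 1 and at 26.8 to 27.1 in the others. Ttr was at 396.9 CPM in control donor leptomeningeal library 4 and at 10.5 to 51.8 in the others. Oligodendrocyte genes took 0.593% of UMIs in control donor microglia library 2 and 0.226% to 0.273% in the others. The tests of differences between genotype effects called 11 lists between donor and host microglia and 11 between donor leptomeningeal cells and donor microglia, and 0 of each with an estimated correlation.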

How the results depend on the processing

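Leaving out both donor microglia libraries that stand apart, the covariates, the scaling to the complement and phagocytosis list and the restriction to genes of a reference population were chosen after seeing the data. Of 4145 values of named genes under alternatives, 3963 were counted as unchanged, 157 lost the call, 25 gained it and 0 reversed. A reversal was counted only for genes that passed in the main test. A change of sign in a gene that passed in neither test counts as unchanged. So does a called gene to which an alternative gave no adjusted p. Of 2155 values of lists called, 196 lost the call and 6 reversed. Spint1 and Commd10 passed under every alternative in donor microglia and in the difference from host microglia, as did Commd10, Spint1, Eps8l1 and Apobec3 in donor leptomeningeal cells, 37 of 38 genes named for donor against host microglia, 33 of 36 for the leptomeninges, and all 30 and 31 for the compartments. In host microglia 0 of 8 did.

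For donor microglia of mutant against control chimeras, the 11 genes became 17 without a low-count filter, 81 with DESeq2, 124 with voom, 4 with these groups alone, 6 without both libraries that stand apart and 4 with the astrocyte and neuron covariate. Leaving out 1 library gave 3 (without control library 1) to 496 (without control library 2). Under that covariate the lists of marrow-derived microglia, astrocytes and oligodendrocytes reversed with adjusted p = 0.861, 0.562 and 0.284 (over the alternatives 0.00405 to 0.861, 7e-35 to 0.562 and 1.12e-07 to 0.392), which its construction explains for astrocytes. For the others the cause was not tested.

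For host microglia the 8 genes became 15 with DESeq2, 5 with voom and 0 with these groups alone, and 0 (without control library 1 or 2 or mutant library 2, 3 or 4) to 11 (without mutant library 1) with 1 library left out. The cause of edgeR's counts of 0 was not tested, and 463 genes had an unadjusted p under 0.05 in all 28 libraries. For donor leptomeningeal cells the 6 genes became 11 with voom, and 7 (without mutant library 2) to 16 (without mutant library 3) lists were called in place of 10. Their homeostatic list went from adjusted p = 7.74e-06 (without mutant library 3) to 0.992 and reversed (without control library 2).

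For host leptomeningeal cells edgeR's 0 genes became 3 with DESeq2's size factors, 2 without a filter, 25 with DESeq2, 17 with these groups alone, 4 with the replicate block and 0 (without control library 1) to 5 (without mutant library 1), where the lone library left is assumed to vary like the other groups. Immediate early genes went from adjusted p = 1.94e-05 (without mutant library 1) to 0.846 and reversed (without mutant library 2), and ribosomal protein genes from 1.76e-05 (without mutant library 2) to 0.882 and reversed (without mutant library 1).

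Between donor and host microglia the 4 genes became 14 with DESeq2, 2 without both libraries that stand apart, and 2 (without control donor library 1) to 63 (without control donor library 2). Between donor compartments the 0 genes became 2 with DESeq2, 1 with voom, 2 with the replicate block, and 0 (without control donor microglia library 1) to 134 (without control donor microglia library 2), and the 11 lists 6 (without control donor microglia library 1) to 13 (without mutant donor microglia library 1). The causes were not tested. Whether replicate numbers pair the samples was not settled: 0 of 6 pairs of groups had every correlation over 0.1 (-0.21 to 0.217). Yet in each genotype 3 of 4 donor leptomeningeal libraries correlated best with the donor microglia library of their own number. In the other pairs of groups it was 0 to 2 of 4. Within genotype comparisons, replicate numbers alone tie control to mutant libraries of different chimeras. With them as a block, H2-Aa passed in host microglia (adjusted p = 0.00541, and 0.00018 to 0.871 over the alternatives), as did Cdk5r1 and Slc44a2 in host leptomeningeal cells (adjusted p = 0.0449 each, and 0.00636 to 0.583 and 0.00361 to 0.583). Cxcr4 lost its call in host microglia (2.127, adjusted p = 0.0692, and 0.0263 to 0.375). In the difference between donor and host microglia H2-Ab1 (-0.885, adjusted p = 0.032, and 0.00604 to 0.795) and H2-Aa (-0.999, adjusted p = 0.0445, and 0.0445 to 0.906) passed with it.

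Called lists with an estimated correlation numbered 0, 2, 0 and 0 for genotype in donor microglia, host microglia, donor and host leptomeningeal cells, 4 and 8 for origin in the parenchyma and leptomeninges, 5 and 12 for the compartments in donor and host cells, and 0 and 0 for the differences between genotype effects. These were 13, 4, 10, 9, 20, 16, 18, 22, 11 and 11 at the preset correlation, in the same order. For origin and compartment, total counts of genes stayed within 1.5 times under every alternative, and counts of lists under every one but the estimated correlation. Among comparisons with 4 libraries per group, that of donor microglia had the fewest UMIs. In simulation it recovered 62% of 2-fold changes in genes at 10 CPM or more, against 88% in host microglia and 80% in donor leptomeningeal cells. Host leptomeningeal groups had more UMIs on average than donor microglia, though not in every library, and with 2 per group 43% were recovered.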

Other observations

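Lists for glucocorticoid and clock genes were written after Per1 and Tsc22d3 had been seen, and the tests of them were chosen after those results, as was the description of donor microglia without control library 2.

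Targets of p53 were lower in donor than in host cells of both compartments: in microglia 11 of 21 were lower and 2 higher (median -0.61; adjusted p = 0.00893, and 0.0483 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 317.1 ± 42.0 CPM in donor and 1876 ± 249.4 in host microglia, and Bax and Bbc3, which promote cell death, at folds of -0.94 ± 0.09 and -1.50 ± 0.17. In leptomeningeal cells 9 of 21 were lower and 3 higher (median -0.48; adjusted p = 0.00815, and 0.0261 with an estimated correlation), with Cdkn1a down by -1.13 ± 0.11. Ribosomal protein genes were higher in donor microglia in 39 of 39 members (median 1.05; adjusted p = 6.35e-18, and adjusted p = 0.0589 with an estimated correlation), and oxidative phosphorylation genes in 44 of 59 with 1 lower (median 0.74; adjusted p = 7.88e-08, and adjusted p = 0.282 with an estimated correlation). Mitochondrially encoded genes, which are not in that list, took 2.658 ± 1.425% of UMIs in control and 3.422 ± 0.7365% in mutant donor microglia, against 0.2406 ± 0.1033% and 0.2188 ± 0.0858% in host microglia. Imprinted genes were higher in donor microglia in 11 of 14 with 1 lower (median 4.18; adjusted p = 0.00703, and adjusted p = 0.245 with an estimated correlation), and lower in donor leptomeningeal cells than in donor microglia in 9 of 14 (median -0.985; adjusted p = 0.0169, and adjusted p = 0.285 with an estimated correlation), the directions of the astrocyte and neuron lists. Cholesterol synthesis genes were higher in host leptomeningeal macrophages than in host microglia in 14 of 19 (median 1.08; adjusted p = 0.0101, and adjusted p = 0.163 with an estimated correlation). Type I interferon genes were higher there in 40 of 43 (median 1.76; adjusted p = 2.2e-12, and adjusted p = 0.0829 with an estimated correlation). The DNA methylation machinery was not called as a list in any contrast, and in mutant against control donor microglia 0 of its 14 members passed (median -0.09, adjusted p = 0.588). Glycolysis genes were higher in donor than in host leptomeningeal cells in 12 of 22 with 3 lower (median 0.73; adjusted p = 0.000402, and adjusted p = 0.113 with an estimated correlation), with the lactate transporter Slc16a3 up by 1.80 ± 0.17. A list's median, mean and test differed in sign in donor against host microglia for TGF-beta signalling (-0.65, 0.05, lower) and complement and phagocytosis genes (-0.30, 0.35, lower), and adjusted p was 0.139 and 0.204.

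Without control donor microglia library 2, 496 genes passed between mutant and control donor microglia, 408 higher and 88 lower. The higher ones included 15 of 17 astrocyte, 10 of 17 neuron, 6 of 12 oligodendrocyte, 15 of 59 oxidative phosphorylation and 8 of 39 ribosomal protein genes, and the lower ones 4 of 18 neutrophil and 4 of 18 monocyte genes.

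It was asked whether mutant donor cells move towards the expression of host cells. Genotype folds of donor leptomeningeal cells had a Spearman correlation across genes of 0.007 with the host minus donor folds of microglia (one-sided exact permutation p = 0.457, highest of the other assignments 0.1, of 70 in all), and those of donor microglia 0.00771 with the host minus donor folds of leptomeningeal cells (exact p = 0.429, highest other 0.109). BH-adjusted over the 6 exact tests run here, both were 0.548. The bound set for a negative answer was an exact p of 0.05 or more, which was wrong, since with 4 libraries per group such a p bounds no effect, so the question stays open.

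A glucocorticoid response may lie behind the rise of Per1 and Tsc22d3 in mutant donor microglia: the mean of 15 other glucocorticoid-responsive genes was higher by 0.294 on the log2 scale (one-sided exact permutation p = 0.0143, the smallest that 70 assignments can give, and 0.0858 BH-adjusted over the 6 tests), with 12 of 15 positive, 5 at an unadjusted p under 0.05 and 0 passing in edgeR. RNA of brain cells stays open as another source: 8 of the 15 were higher in donor than in host microglia and 5 of the 15 lower in donor leptomeningeal cells than in donor microglia. With the astrocyte and neuron covariate Per1 and Tsc22d3 had folds of 1.115 ± 0.25 and 0.936 ± 0.214, against 1.234 ± 0.203 and 0.844 ± 0.17 without it, and neither passed (adjusted p = 0.117 each, with 1.3e-05 to 0.117 and 0.00135 to 0.235 over the alternatives), with larger SEs. In host microglia the difference was 0.0925 (exact p = 0.0571, BH 0.171; 11 of 15 positive). Clock phase, from 12 genes, differed by 0.383 in donor (two-sided exact p = 0.4, BH 0.548) and 0.153 in host microglia (exact p = 0.629, BH 0.629), and the bound on p was wrong for the same reason, so a difference in clock phase cannot be told apart from chance with 4 libraries per group.

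Splits of the same libraries into other groups of the same sizes were refitted. Chance cannot be excluded for the number of genes in the 3 genotype comparisons with 4 libraries per group: in donor microglia 4 of 35 splits reached the real 11 (highest other 531), in host microglia 2 of 35 the real 8 (highest other 13), and in donor leptomeningeal cells 2 of 35 the real 6 (highest other 46), where a share under 0.05 needs the real split alone (0.0286). Host leptomeningeal cells, with 2 libraries per group, were not split. For the difference of genotype effects between donor and host microglia it cannot be excluded either, with 7 of 100 at the real 4 (highest other 32). Between donor compartments the real count was 0, which all 100 of 100 splits reach by construction (highest other 111), so that count tests nothing. The split with 531 genes set control libraries 1, 3 and 4 with mutant library 1 against the rest, which are the 4 lowest astrocyte shares (0.145% to 0.401%, against 0.437% to 0.725%). The one with 46 set control library 1 with mutant libraries 1, 2 and 4 against the rest, the 4 lowest neutrophil shares (3.71% to 5.68%, against 6.04% to 9.97%), so both point to a structure of the samples other than genotype. Chance can be excluded for origin and compartment, where 1 of 100 splits, the real one, reached 7448 genes in microglia (highest other 5612), 3718 in leptomeninges (highest other 2039), 7650 in donor cells (highest other 5702) and 6994 in host cells (highest other 3712). For lists, the real split alone reached its count for origin in microglia (1 of 100 at 20, highest other 19) and compartment in host cells (1 of 100 at 22, highest other 21). These margins are so small that the list count hardly separates real from other splits, and a split of host cells with 0 genes called had 21 lists. Chance cannot be excluded for lists in origin in leptomeninges (13 of 100 at 16, highest other 17) and compartment in donor cells (22 of 100 at 18, highest other 20). Nor can it for genotype in donor microglia (7 of 35 at 13, highest other 19), host microglia (13 of 35 at 4, highest other 8) and donor leptomeningeal cells (16 of 35 at 10, highest other 19). The same holds for the differences of genotype effects between origins (14 of 100 at 11, highest other 16) and compartments (30 of 100 at 11, highest other 17).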
